A study of Rattus norvegicus with 12 samples.

How the data were processed

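RNA was sequenced from the hippocampus of Sprague Dawley rats. Their stated age is 6 to 7 weeks, and whether that was before or after the 5 weeks of stress is not established here. Per the labels, tissue was snap-frozen, RNA was extracted with TRIzol, and 3 µg of it entered a standard Illumina library. Samples were assigned to the 4 groups of 3 by their titles. Per the submitters' processing notes, TopHat2 and the rat build rn6 were used; the version, the read counter, the annotation release, the strand setting and the way rows without an Ensembl ID arose are not given in the sources used here.

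The authors deposited a table of FPKM, reads scaled by gene length and by the library's total, for 28959 rows in 12 columns named as the samples. The deposited header names no unit. FPKM was read from the values, since column totals differ and each gene's values are whole multiples of the worth of 1 read. Of the rows, 27068 carry Ensembl rat gene IDs and 1891 do not, and 6222 were at 0 in all 12 samples. The lengths and reads behind the FPKM were recovered by finding, for each gene, 1 whole length in bp and whole reads per sample that gave its values at 1 total per sample. This succeeded for 22737 of the 22737 rows above 0 (100%), with whole meaning within 0.0001 of a read. Recovered reads summed to about 99.99% of each total. Reads of a rare sparse gene can be understated by a common factor. Tested on simulated data, the step returned the totals of 12 of 12 simulated samples and the reads of 99.98% of 15669 simulated genes with a mean of at least 10 reads. Depth was 14735953 to 18109623 reads per sample. Within pairs of replicates, the squared difference in a gene's reads was a median of 2.17 to 6.55 times that of counting noise, so counting error is a sizeable part of the spread for many genes.

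Values were tested on the scale log2(FPKM + 0.5), which understates the change of low genes, over the 15253 rows with a mean of at least 0.5 FPKM over all samples. Limma 3.58.1 in R 4.3.3, with a trend of variance with level and robust settings, fitted all 12 samples with 1 coefficient per group, so that the 4 groups share 1 estimate of the spread. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a single gene is from this fit or a named alternative. The design was written before the data were examined with a branch for counts and one for FPKM, and the latter was used. Principal components were taken of the same log2 values. Group shares and medians were compared by exact two-sided permutation, which cannot go below 0.1 for 3 against 3. Reads were compared between replicates by chi-square, and the variation exceeded counting noise in every pair, so no library was counted as a copy of another. On simulated reads for CUMS-Sal against Ctrl-Sal over 15253 genes, with 200 changed, the fit recovered 58% of 50 genes changed 1.5-fold, 86% at 2-fold, 96% at 3-fold and 98% at 4-fold, and 11 of 180 calls (6.11%) were false. With fewer changed genes the adjusted p asks for a smaller unadjusted p. The recovered shares therefore do not carry over to the drug comparisons, where 0 calls do not exclude such changes. Chance relations between comparisons that share libraries were taken from 100 simulated sets of unchanged groups. These gave a covariance of about the same size whichever group was shared, as with 1 spread for all groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.

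The rule for named genes, written before the data were examined, took per comparison the called genes of smallest p with non-overlapping groups that carry a symbol, and the genes of smallest unadjusted p where few were called. Neither the table nor the reference used here pairs the Ensembl IDs with symbols (0 IDs matched). The rule was therefore applied to IDs, up to 2 per direction in a comparison. ENSRNOG00000019050 in CUMS-Alb against Ctrl-Sal and ENSRNOG00000056350 in CUMS-Flx against Ctrl-Sal fall outside the rule and were chosen after their values were seen. The gene lists and cell type markers fixed beforehand could not be matched to any row and were not tested, so no pathway or cell type is described. Genes that share reads with near-identical copies or overlap others could not be set apart.

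Alternatives planned beforehand were limma without trend and robust settings, quantile normalization, no filter above 0, a minimum mean of 5 FPKM, pseudocounts of 0.1 and 1, a fit of only the groups compared, the replicate number as a block, an adjusted p under 0.1 and leaving out each library. Chosen after seeing the data were limma-voom on recovered reads (mean of at least 10), library medians set equal, rescaling outside the 9 abundant genes, the median deviation of each library set to 0, 1 spread per group by array weights, and removal of a smooth trend with gene length, alone or with the library mean. The version with the library mean was the first, and the other was added after its result was seen. The measures of stress genes per library, the genes chosen without 1 CUMS-Sal library, and the relations between comparisons without CUMS-Flx replicate 1 or Ctrl-Sal replicate 2, were also chosen then. The fluoxetine dose is 10 mg/kg/d in the sample labels and 7 mg/kg/d in the series text.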

Results

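Gene expression was measured by RNA sequencing in the hippocampus of Sprague Dawley rats in 4 groups of 3 libraries. Ctrl-Sal rats were not stressed and received saline. The other rats went through chronic unpredictable mild stress (CUMS), a rodent procedure of changing mild stressors used as a model of depression, for 5 weeks, and received saline (CUMS-Sal), fluoxetine (CUMS-Flx) or albiflorin (CUMS-Alb) for the last 7 days. Fluoxetine is a serotonin reuptake inhibitor used as an antidepressant, and albiflorin is a monoterpene glycoside from peony root. The libraries held 14735953 to 18109623 reads assigned to genes, as recovered from the deposited FPKM values. The labels do not say that the 3 libraries of a group came from separate rats, so p-values measure only the spread between these libraries, which may be partly technical. The deposited table does not pair its gene IDs with names, so genes are described by group, and single ones by ID.

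Along the largest direction of variation, Ctrl-Sal replicate 2 lay far from the other libraries. Principal component 1 held 36% of the variance of 15253 genes and ran from Ctrl-Sal replicate 2, at -44.7, to CUMS-Sal replicate 2, at 15.1. The other Ctrl-Sal libraries lay at -12.2 and -7.8, the CUMS-Sal libraries at 8.8 to 15.1, the CUMS-Alb libraries at 6.1 to 12.3 and the CUMS-Flx libraries at -9.9 to 7.2. The median correlation of Ctrl-Sal replicate 2 with the other libraries was 0.977, against 0.989 to 0.992 for the rest. Across genes, the median SD between replicates was 0.15 log2 units in Ctrl-Sal and 0.11, 0.11 and 0.10 in CUMS-Sal, CUMS-Flx and CUMS-Alb.

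**Figure D1:**
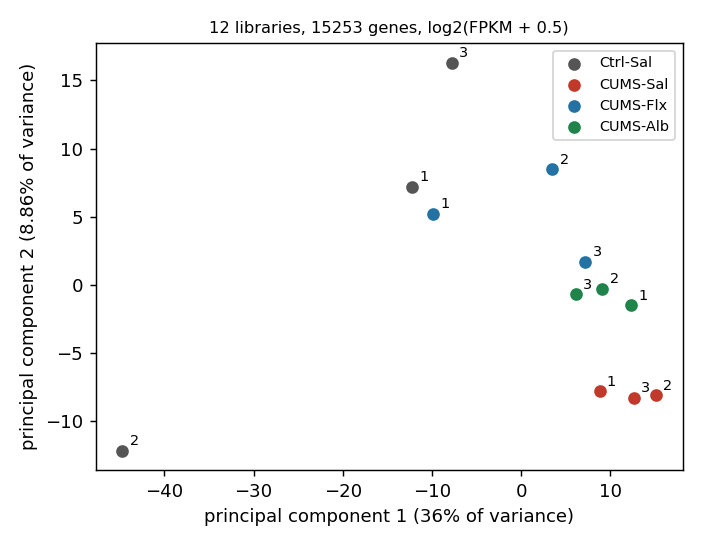
Principal components 1 and 2 of log2(FPKM + 0.5) over the 12 libraries, 1 point per library with its replicate number and coloured by group; both axes are scores with no unit. Ctrl-Sal replicate 2 lies apart at -44.7 on component 1, and CUMS-Flx replicate 1 lies at -9.9, between Ctrl-Sal replicates 1 and 3.

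The comparison of CUMS-Sal with Ctrl-Sal asks which hippocampal transcripts differ after stress. In CUMS-Sal 1228 genes were higher and 174 lower, and the called changes were mostly modest, with a median log2 change of 0.50 among the higher and -0.37 among the lower genes. Fold changes here are of FPKM + 0.5, not of the FPKM means printed beside them. A change of over 1.5-fold was reached by 426 higher and 21 lower genes, and one of over 2-fold by 73 and 4. ENSRNOG00000037886 was 2.89-fold higher, at 4.69 ± 0.336 FPKM against 1.34 ± 0.513 (SD, n = 3; log2 change 1.53, SE 0.17, adjusted p = 0.0127), and ENSRNOG00000014215 was 1.47-fold higher, at 61.6 ± 2.94 against 41.8 ± 2.66 FPKM (log2 change 0.56, SE 0.07, adjusted p = 0.0127). ENSRNOG00000055068 was 2.6-fold lower, at 10.0 ± 0.927 against 27.5 ± 7.78 FPKM (log2 change -1.38, SE 0.19, adjusted p = 0.0161), and ENSRNOG00000014654 was 1.29-fold lower, at 42.8 ± 1.6 against 55.5 ± 2.64 FPKM (log2 change -0.37, SE 0.06, adjusted p = 0.0161).

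Higher and lower calls were divided differently by gene length and level. Of genes of up to 1600 bp 311 were higher and 131 lower in CUMS-Sal, of genes of 1600 to 2800 bp 398 and 36, and of longer genes 519 and 7. By mean level 233 were higher and 18 lower up to 3.72 FPKM, 516 and 28 from there to 15.4 FPKM, and 479 and 128 above. Over all 15253 genes the relation was weak, at a Spearman correlation of the log2 change of 0.12 with length and -0.0944 with level. The 9 genes that each took over 1% of the reads, all between 681 and 1830 bp long, together held 20% ± 2.32 of the reads in Ctrl-Sal and 14.9% ± 0.157 in CUMS-Sal (SD, n = 3). This share did not overlap between the groups (exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow; 0.2 after Benjamini-Hochberg adjustment over 6 comparisons). Of these 9 genes 6 were called lower in CUMS-Sal, with log2 changes of -0.56 to -0.32 for the 9. Only quantile normalization, which sets the values at each rank equal between libraries, moved the 9 to -0.03 to 0.06; under the 5 other scalings and length corrections they stayed lower. Of 1346 tested rows without an Ensembl ID, median 1.35 FPKM, 4.61% were called, against 9.64% of 13907 rows with one, median 9.36 FPKM (two-sided Fisher's exact p = 5.15e-11 and 3.09e-10 after Benjamini-Hochberg adjustment over 6 comparisons, across genes, which are not independent). Among all tested genes of up to 3.72 FPKM 4.94% were called, so this difference was not set apart from one by level.

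The excess of higher over lower genes in CUMS-Sal depended on the scaling. The median change of all tested genes was 0.10 on the log2 scale. Relative to that shift, with the median deviation of each library set to 0, 364 genes were higher and 379 lower, and the log2 changes were 1.43 for ENSRNOG00000037886, 0.45 for ENSRNOG00000014215, -1.48 for ENSRNOG00000055068 and -0.47 for ENSRNOG00000014654, all still called. The difference by length held on that scale, at 115 higher and 243 lower among the short genes and 148 and 24 among the long ones, and 8 of the 9 abundant genes were called lower. With library medians set equal 332 genes were higher and 622 lower, and after quantile normalization 297 and 232. Of the 1402 genes called in the main fit, 38.4% were called again in the same direction with deviations set to 0. The share was 36.1% with library medians set equal and 30.8% after quantile normalization.

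The number of genes called depended on single libraries. Of 15253 genes, 4572 (30%) had an unadjusted p under 0.05. In 4749 (31.1%) the CUMS-Sal and Ctrl-Sal libraries did not overlap, where chance gives 10% on average. Genes are not independent, so by chance alone this share can lie far from 10%, here and in the later comparisons. The smallest adjusted p was 0.0127, so many genes lay near the threshold. The 1402 calls became 369 without Ctrl-Sal replicate 2, 2637 without Ctrl-Sal replicate 3, and 327, 1 and 24 without CUMS-Sal replicates 1, 2 and 3. In these 5 fits the median absolute log2 change of the 1402 genes, which were chosen with all libraries, was 0.38 to 0.55, against 0.48. With only the CUMS-Sal and Ctrl-Sal libraries in the limma fit 0 genes were called, and with 1 spread per group 454 were. Other fits held the count better. Limma-voom on recovered reads called 1848 genes, with 93.2% of the 1402 called again in the same direction. Without Ctrl-Sal replicate 1 the count was 1280, with 69% called again. The 4 named IDs lost their calls without CUMS-Sal replicate 2 (adjusted p = 0.0668 for the higher and 0.0708 for the lower ones, log2 changes 1.48, 0.52, -1.33 and -0.34) and in the fit of only the compared groups (adjusted p = 0.126), the highest values over their alternatives, which reached down to 0.000523, 0.00403, 0.00469 and 0.00674.

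For fluoxetine, CUMS-Flx was compared with CUMS-Sal. As a median over the genes called in CUMS-Sal, CUMS-Flx stood closer to Ctrl-Sal than CUMS-Sal did, and 0 genes were called by limma one by one. The 1228 genes higher in CUMS-Sal stood, as a median per library, 0.21, 0.34 and 0.39 log2 units above the Ctrl-Sal mean in CUMS-Flx and 0.47 to 0.53 above it in CUMS-Sal. The 174 lower genes stood at -0.15, -0.26 and -0.29 in CUMS-Flx and at -0.41 to -0.34 in CUMS-Sal. Single genes did not all follow: 72 of the higher genes, ENSRNOG00000057823 and ENSRNOG00000001044 among them, stood above CUMS-Sal in CUMS-Flx, and 22 of the lower ones below it. These genes were chosen with the CUMS-Sal libraries, which enlarges the differences, so no p is given. With the 1000 genes of smallest p chosen without CUMS-Sal replicate 1, 2 or 3, the higher ones differed between CUMS-Flx and the left-out library by a median log2 of -0.08, -0.19 and -0.13, against -0.05, -0.05 and -0.06 for all genes, and the lower ones by 0.04, 0.13 and 0.02. The left-out library itself stood 0.42, 0.48 and 0.43 above Ctrl-Sal over the higher genes. The 9 abundant genes held 16.5% ± 1.99 of the reads in CUMS-Flx (18.8, 15.5 and 15.3% in replicates 1, 2 and 3), with 0 of them called against CUMS-Sal.

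In the limma fit 1523 genes (9.98%) had an unadjusted p under 0.05 between CUMS-Flx and CUMS-Sal, and limma-voom on recovered reads also called 0. The libraries did not overlap in 2726 genes (17.9%, chance 10%). The gene of smallest p was ENSRNOG00000056350, 139 bp long, at 2.21 ± 0.154 FPKM in CUMS-Flx and 6.05 ± 0.518 in CUMS-Sal (SD, n = 3; log2 difference -1.27, SE 0.16, adjusted p = 0.0548). These values rest on 5, 5 and 6 recovered reads in CUMS-Flx and 12, 14 and 13 in CUMS-Sal. At so few reads the SDs lie below counting error, so the SE is likely too small. The gene was called under 6 alternatives at the same threshold, quantile normalization, a pseudocount of 0.1, a fit of only these groups, library medians set equal, rescaling outside the 9 abundant genes and deviations centred at 0. It was not called by limma-voom, and its adjusted p ran from 0.00345 to 0.455. Ctrl-Sal, at 5.39 ± 0.741, and CUMS-Alb, at 5.39 ± 1.43, lay near CUMS-Sal. Without CUMS-Sal replicate 2, 1 gene was called, and with only the CUMS-Flx and CUMS-Sal libraries in the fit 5 were.

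Stress and fluoxetine changes were negatively correlated across genes, and sharing the CUMS-Sal libraries alone gives much of this. Their log2 changes correlated at r = -0.576 across 15253 genes, which are not independent, with 26.2% of genes of the same sign, and unchanged groups simulated with shared CUMS-Sal libraries gave -0.499 and 33.3%. The covariance was -0.0289 against a simulated -0.0117. The simulation behaved as with 1 spread for all groups, while the median SD was 0.151 log2 units in Ctrl-Sal and 0.108 in CUMS-Sal. A noisier Ctrl-Sal weakens the r of unchanged groups, so the simulated r and shares of sign are likely too strong. Without CUMS-Flx replicate 1, r was -0.425 and 34.2% had the same sign, against the -0.447 and 35.2% simulated for that case, with a covariance of -0.0218 against -0.0117. Without Ctrl-Sal replicate 2 they were -0.561 and 26.3% against -0.442 and 35.3%, with -0.0247 against -0.0116. No gene called in CUMS-Sal was called back in CUMS-Flx (0 of 1402), which follows from the 0 calls for the drug. The 3 CUMS-Sal libraries are too few to be split into parts of 2 or more, so part of the relation may come from sharing them.

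For albiflorin, CUMS-Alb was compared with CUMS-Sal, and no single gene passed the test. The 1228 genes higher in CUMS-Sal stood 0.39 to 0.45 log2 units above the Ctrl-Sal mean in the CUMS-Alb libraries, below the 0.47 to 0.53 of CUMS-Sal, and the 174 lower genes at -0.30 to -0.29. Here too single genes went the other way, with 237 of the higher genes above CUMS-Sal in CUMS-Alb and 31 of the lower ones below it. The genes were again chosen with the CUMS-Sal libraries. Against a left-out CUMS-Sal library the differences had no steady direction, at 0.02, -0.07 and -0.03 for the genes chosen as higher (-0.01, 0.00 and -0.02 for all genes) and -0.01, 0.08 and -0.04 for those chosen as lower. The 9 abundant genes held 15.1% ± 0.485 of the reads in CUMS-Alb and 14.9% ± 0.157 in CUMS-Sal (SD, n = 3; exact two-sided permutation p = 0.7, also after adjustment). ENSRNOG00000019050, of smallest p, was nearly absent from CUMS-Alb, at 0.0313, 0 and 0 FPKM, and stood at 1.45 ± 0.362 in CUMS-Sal (log2 difference -1.91, SE 0.28, adjusted p = 0.2), but was called with a pseudocount of 0.1 (adjusted p = 0.00188) and with only these groups in the fit (adjusted p = 0.0224). Over its alternatives the adjusted p ran from 0.00188 to 1.

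By limma 0 genes were called between CUMS-Alb and CUMS-Sal, 559 (3.66%) had an unadjusted p under 0.05, and limma-voom called 0. The libraries did not overlap in 1716 genes (11.3%, chance 10%). With only the CUMS-Alb and CUMS-Sal libraries in the fit 4 genes were called, and without CUMS-Sal replicate 2 there was 1. The stress and albiflorin changes correlated at r = -0.408 across genes, against a simulated -0.498, with a covariance of -0.0176 against -0.0116. As for fluoxetine, the simulated r is likely too strong, since Ctrl-Sal spread more than the simulation allowed for. With 0 calls, none of the 1402 stress calls could be called back with albiflorin and none could be shared by the drugs.

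**Figure D2:**
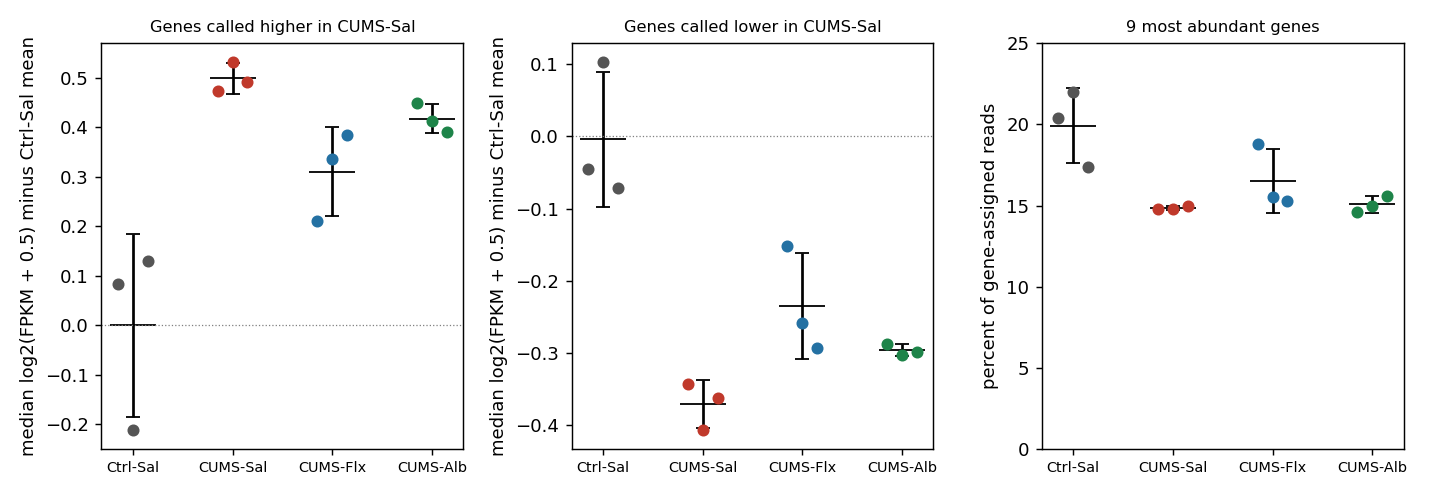
Points are the 12 libraries by group, with the group mean as a line and the SD as a bar (n = 3). The panels give the median log2(FPKM + 0.5) minus the Ctrl-Sal mean over the 1228 genes called higher and over the 174 called lower in CUMS-Sal, and the percent of gene-assigned reads in the 9 most abundant genes, where Ctrl-Sal lies at 17.4 to 22.0% and CUMS-Sal at 14.8 to 15%.

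The drugs were compared directly in CUMS-Alb against CUMS-Flx, and 1 gene differed. ENSRNOG00000019050 had 1, 0 and 0 recovered reads in the CUMS-Alb libraries, 109, 45 and 161 in CUMS-Flx, 60, 42 and 37 in CUMS-Sal and 42, 37 and 46 in Ctrl-Sal. Against CUMS-Flx its log2 change was -2.62 on the log2(FPKM + 0.5) scale (SE 0.28, adjusted p = 0.00738, lower in 3 of 3 libraries). Relative to the libraries' totals, the ratio of its reads in CUMS-Alb to those in CUMS-Flx was 0.00332, with an exact 95% interval of 8.38e-05 to 0.0186 that covers counting error only. In CUMS-Alb the gene was also called lower than in Ctrl-Sal (log2 change -1.82, SE 0.28, adjusted p = 0.0385). The 1228 genes higher in CUMS-Sal stood 0.42 ± 0.03 above Ctrl-Sal in CUMS-Alb and 0.31 ± 0.09 in CUMS-Flx (SD, n = 3; exact two-sided permutation p = 0.1, the smallest possible), and relative to the median of all genes at 0.32 ± 0.02 and 0.26 ± 0.06 (exact p = 0.2). The 174 lower genes stood at -0.30 ± 0.01 in CUMS-Alb and -0.23 ± 0.07 in CUMS-Flx (exact p = 0.2), and relative to the median of all genes at -0.39 ± 0.01 and -0.29 ± 0.10 (exact p = 0.1). The stated dose was 7 mg/kg/d for albiflorin, and for fluoxetine 10 mg/kg/d in the sample labels and 7 mg/kg/d in the series text.

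In all, 759 genes (4.98%) had an unadjusted p under 0.05 between CUMS-Alb and CUMS-Flx, and 2094 (13.7%, chance 10%) did not overlap. The call of ENSRNOG00000019050 ended without CUMS-Alb replicate 3 (adjusted p = 0.0706, log2 change -2.60) and with only these groups in the fit (adjusted p = 0.0639); over its alternatives the adjusted p ran from 4.08e-05 to 0.0706. The count was 0 without CUMS-Alb replicate 3, 3 and 2 without CUMS-Alb replicates 1 and 2, and 2 without CUMS-Flx replicate 1.

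**Figure D3:**
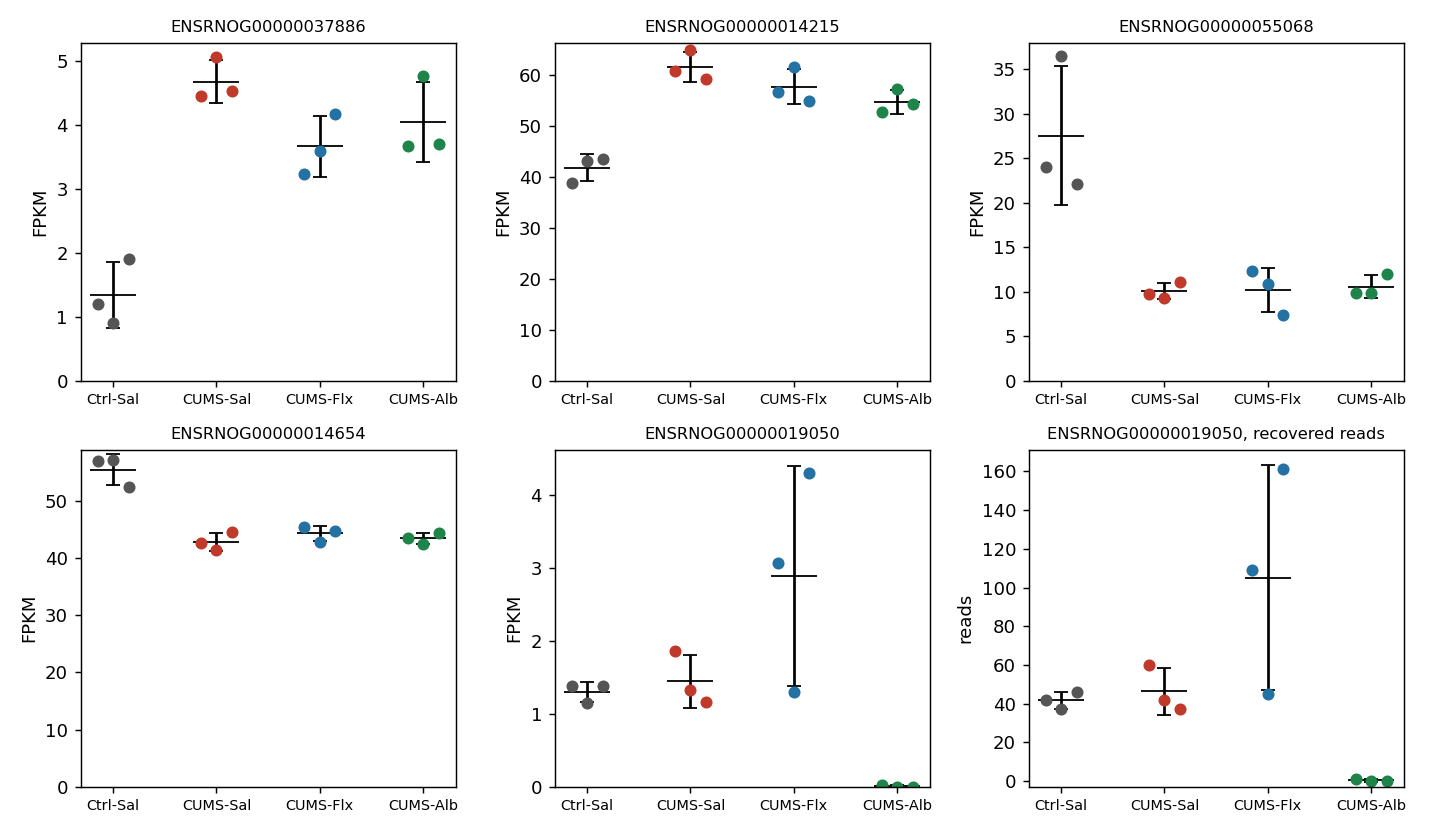
Points are the 12 libraries by group, with the group mean as a line and the SD as a bar (n = 3), for 5 genes in FPKM and for ENSRNOG00000019050 also in recovered reads. ENSRNOG00000037886 and ENSRNOG00000014215 are higher and ENSRNOG00000055068 and ENSRNOG00000014654 lower in CUMS-Sal than in Ctrl-Sal, and ENSRNOG00000019050 has at most 1 read in each CUMS-Alb library and at least 37 elsewhere.

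Stressed rats given a drug were also set against unstressed rats. CUMS-Alb had 332 genes higher and 49 lower than Ctrl-Sal. ENSRNOG00000057823 was higher, at 22.5 ± 0.939 against 15.6 ± 0.616 FPKM (SD, n = 3; log2 change 0.52, SE 0.07), as was ENSRNOG00000037886, at 4.05 ± 0.622 (1.34, SE 0.17). ENSRNOG00000055068 was lower, at 10.6 ± 1.25 (-1.31, SE 0.19), as was Novel01763, a row without an Ensembl ID, at 4.85 ± 0.609 against 8.34 ± 0.315 (-0.73, SE 0.11), each of the 4 at an adjusted p of 0.0385. Of genes of up to 1600 bp 69 were higher and 39 lower, and of genes over 2800 bp 168 and 2. The 381 calls shared 317 genes, in the same direction, with the 1402 in CUMS-Sal. Independent lists would share 27.3, but these lists share the Ctrl-Sal libraries, and simulated unchanged groups give no calls to compare. The log2 changes correlated at r = 0.815 (simulated 0.5), with a covariance of 0.0553 (simulated 0.0117), and part of the excess may come from the shared Ctrl-Sal libraries, which are too few to split. Ctrl-Sal spread more than the groups compared with it (median SD 0.151 log2 units, against 0.108 in CUMS-Sal and 0.095 in CUMS-Alb). The simulation behaved as with 1 spread for all groups, so its values are likely too low here. With the median deviation of each library set to 0, 10 genes were higher and 18 lower, with library medians set equal 51 and 106, after quantile normalization 50 and 48, and after rescaling to the FPKM total outside the 9 abundant genes 100 and 33.

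The count for CUMS-Alb against Ctrl-Sal also rested on single libraries, with 4185 genes (27.4%) at an unadjusted p under 0.05 and 4730 (31%, chance 10%) not overlapping. It was 6 without Ctrl-Sal replicate 2, 2356 without Ctrl-Sal replicate 3, and 1, 0 and 0 without CUMS-Alb replicates 1, 2 and 3. Limma-voom on recovered reads called 1221, limma with 1 spread per group 4, and limma without its trend and robust settings 0. The calls of the 4 IDs and of ENSRNOG00000019050 ended without CUMS-Alb replicate 1 (adjusted p = 0.141), replicate 2 (0.124) or replicate 3 (0.088 to 0.0963), and those of ENSRNOG00000055068, Novel01763 and ENSRNOG00000019050 also without Ctrl-Sal replicate 2 (0.0575 to 0.06). In those of these fits that ended its call, the log2 change of each was 0.50 to 0.55 for ENSRNOG00000057823, 1.22 to 1.39 for ENSRNOG00000037886, -1.40 to -1.09 for ENSRNOG00000055068, -0.78 to -0.63 for Novel01763 and -1.88 to -1.80 for ENSRNOG00000019050. Over all alternatives the adjusted p ran, in the same order, from 0.0124 to 0.141, 0.00402 to 0.144, 0.0124 to 0.141, 0.0136 to 0.141 and 0.0027 to 0.141.

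CUMS-Flx had 5 genes higher and 3 lower than Ctrl-Sal. ENSRNOG00000057823 had the smallest p and was higher, at 24.4 ± 1.64 against 15.6 ± 0.616 FPKM (SD, n = 3; log2 change 0.63, SE 0.07, adjusted p = 0.00816), as was ENSRNOG00000001044, at 26.8 ± 1.66 against 18.6 ± 1.03 (0.52, SE 0.06, adjusted p = 0.0227). ENSRNOG00000055068 was lower, at 10.2 ± 2.51 against 27.5 ± 7.78 (-1.38, SE 0.19, adjusted p = 0.0298), as was ENSRNOG00000032297, at 49.2 ± 4.34 against 68.1 ± 3.23 (-0.47, SE 0.07, adjusted p = 0.0298). Of the 8 calls 6 were shared with CUMS-Sal in the same direction. Independent lists would share 0.437, which leaves out the shared Ctrl-Sal libraries. The log2 changes correlated at r = 0.73 (simulated 0.498), with a covariance of 0.0439 (simulated 0.0116), and part of the excess may come from sharing these libraries. As for CUMS-Alb, the larger spread of Ctrl-Sal likely makes the simulated values too low. The limma fit had 2666 genes (17.5%) at an unadjusted p under 0.05, and 2696 (17.7%, chance 10%) did not overlap. The higher and lower counts were 10 and 14 after quantile normalization, 7 and 15 with library medians set equal, and 3 and 7 with deviations centred at 0 or with rescaling outside the abundant genes. The count was 14, 1 and 544 without Ctrl-Sal replicates 1, 2 and 3, and 5, 2 and 1 without CUMS-Flx replicates 1, 2 and 3. Voom called 54. ENSRNOG00000057823 stayed called without each of the 6 libraries in turn (adjusted p = 0.0106 to 0.0436) and was not called in some other fits, such as that of only these groups (0.398), and over all alternatives its adjusted p ran from 0.00306 to 0.398. The other 3 lost their calls in more fits, among them those without Ctrl-Sal replicate 2 (0.0518), without CUMS-Flx replicate 2 or 3 (0.0693 to 0.155), with 1 spread per group (0.0629 to 0.0917), without trend and robust settings (0.075 to 0.0904) and with only these groups in the fit (0.407, the highest of all). ENSRNOG00000001044 also lost it without CUMS-Flx replicate 1 (0.0542), and the 2 lower ones with no filter (0.0603). The lowest adjusted p of the 3 were 0.0107, 0.0116 and 0.0198, and their log2 changes 0.43 to 0.56, -1.53 to -1.17 and -0.55 to -0.43. The remaining lower call was ENSRNOG00000056350 (log2 change -1.12, SE 0.16, adjusted p = 0.0298). It rested on 5, 5 and 6 recovered reads in CUMS-Flx and 10, 11 and 14 in Ctrl-Sal, so its SE is likely too small. Limma-voom did not call it (adjusted p = 0.105), and over all alternatives its adjusted p ran from 0.0232 to 0.316.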

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

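The tests of explanations here were set after the change of this gene was known, and before their own results were seen. The effects of the 2 drugs relative to CUMS-Sal differed for 1 gene by a test of the difference itself, ENSRNOG00000019050, lower in CUMS-Alb than in CUMS-Flx by a log2 change of -2.62 (limma, adjusted p = 0.00738, n = 3 per group). With at most 1 read in each CUMS-Alb library, the size of this change depends on the pseudocount. It ran from -6.963 to -1.862 over the alternatives. Counting error is excluded, since the exact interval of the ratio of reads ends at 0.0186, far from 1. The call ended without CUMS-Alb replicate 3 (adjusted p = 0.0706, highest over the 6 libraries left out in turn), where 2 libraries remained and the log2 change was -2.60. A candidate explanation is that some rats of this outbred strain lack or carry a transcript whatever their group. It predicted at least 5 other genes near absent in libraries that are not whole groups, and 4 were found, too few by that bound and more than the 0 that would exclude it, so a drug effect and such a difference between rats cannot be told apart. Of the 10 splits of the 6 libraries, too few for a share under 0.05, the real one gave 1 call and the highest other 0.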

How the results depend on the processing

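The scalings, limma-voom, the spread per group and the length corrections were chosen after seeing the data. Of the alternatives for the log2 changes of single genes, 421 kept direction and side of the threshold, 110 lost the call, 9 gained it and 0 reversed, while counts of calls above 0 in the main fit stayed within 1.5 times in 34 cases and moved further in 54. Counts of 0 stayed 0 in 113 cases and rose in 15. Many of these cases are stress calls moved back and calls shared by the drugs, which must be 0 wherever a drug comparison has no calls. The cause was not tested unless fewer libraries or more tested genes enter by construction. For CUMS-Sal against Ctrl-Sal the 1402 calls became 740 without trend and robust settings, 529 after quantile normalization, 251 with no filter (22737 genes), 0 with only the groups compared, 3173 at an adjusted p under 0.1, 743 with deviations centred at 0, 454 with 1 spread per group, 626 with length trend and library mean removed, and 1 to 2637 leaving out a library. For CUMS-Alb against Ctrl-Sal the 381 became 0 without trend and robust settings, 98 after quantile normalization, 3 with no filter, 996 with the stricter filter, 1 with only the groups compared, 2373 at an adjusted p under 0.1, 1221 by voom, 157 with medians equal, 133 rescaled outside the abundant genes, 28 with deviations centred, 4 with 1 spread per group, 136 with the length trend removed, 41 with the library mean also removed, and 0 to 2356 leaving out a library. For CUMS-Flx against Ctrl-Sal the 8 became 1 without trend and robust settings, 24 after quantile normalization, 3 with no filter, 0 with only the groups compared, 129 at an adjusted p under 0.1, 54 by voom, 22 with medians equal, 1 with 1 spread per group, and 1 to 544 leaving out a library. For CUMS-Flx against CUMS-Sal the limma count of 0 (1523 at an unadjusted p under 0.05, 0 by voom) became 5 with only the groups compared, 1 with quantile normalization, a pseudocount of 0.1, an adjusted p under 0.1, medians equal, rescaling or deviations centred, and 0 to 1 leaving out a library. For CUMS-Alb against CUMS-Sal the 0 (559 unadjusted, 0 by voom) became 1 with a pseudocount of 0.1, 4 with only the groups compared, and 0 to 1 leaving out a library. For CUMS-Alb against CUMS-Flx the 1 became 0 with the stricter filter, which drops the gene, 2 with only the groups compared, and 0 to 3 leaving out a library. Stress calls moved back by fluoxetine or by albiflorin, and calls shared by the drugs, were 0, and 0 to 1 leaving out a library. Replicate numbers do not pair the samples: deviations of 18 same-numbered pairs correlated at -0.159 to 0.127, 1 of them over 0.1. The replicate block gave 565 calls for CUMS-Sal, 0 for CUMS-Alb and 0 for CUMS-Flx against Ctrl-Sal, and moved no other count by over 1.5 times. A library left out of a group of 3 leaves 2, and the spread is pooled over groups. Tests of gene lists were not run for want of matching names, nor was the inter-gene correlation, and count models were not run on FPKM, for which limma-voom on recovered reads was the nearest. At 14735953 to 18109623 reads, counting error adds to the spread of many genes.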

Other observations

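The length test and the rescaling and centring tests were chosen after the data had been seen. Besides ENSRNOG00000019050, 4 genes had 2 reads or fewer in some libraries and at least 30 in all others. ENSRNOG00000060523 (70 to 102 reads) and ENSRNOG00000026051 (55 to 109 reads) were on in the same 5 libraries, Ctrl-Sal replicate 2, CUMS-Sal replicate 1, CUMS-Flx replicates 1 and 3 and CUMS-Alb replicate 1, and near absent in the same 7. Each group thus held libraries of both kinds, which argues against all 3 libraries of a group being repeats of a single RNA sample. Whether each library came from its own rat stays open. ENSRNOG00000039744 was near absent only in Ctrl-Sal replicate 2, and ENSRNOG00000060518 had 44 reads in Ctrl-Sal replicate 3 and at most 1 in each other library. These IDs were chosen after their values were seen.

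More genes rose than fell in CUMS-Sal against Ctrl-Sal. The 9 abundant genes held 14.9% of the reads in CUMS-Sal and 20% in Ctrl-Sal. As FPKM are scaled by the library's total, this by construction raises the other genes' FPKM in CUMS-Sal on average. How much of the excess of higher genes it accounts for stays open. After each library was rescaled to its FPKM total outside the 9 genes, 79.2% of calls were still higher. By the bound set before this result, 79.2% counted against this cause. The rescaling does not remove the share of reads itself, so it cannot decide. It left a median log2 change of 0.066 over all tested genes, against 0.103 in the main fit. A trend with gene length stays open. Its removal left 88.5% higher, but that step keeps each library's level and with it the common shift. A first version, replaced after its result was seen, also removed the library mean and left 46.3% higher, but it takes the shift away, so neither version can decide. A shift common to all genes also stays open. Setting library medians equal left 34.8% higher, but that step itself removes such a shift, so its result cannot tell a technical shift from one of biological origin.

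The count of 1402 calls between CUMS-Sal and Ctrl-Sal may partly reflect a difference between libraries that also exists within groups. Across genes the stress change correlated with the difference of CUMS-Flx replicate 1 from the other CUMS-Flx libraries at r = -0.332, an absolute value of 0.332 and the largest of the 6 drug libraries, the others lying between -0.124 and 0.247. This fits the explanation and leaves open whether the shared direction is tissue taken, RNA handling or the rats' own state. Ctrl-Sal replicate 2 as the source cannot be told apart from a general lack of precision, since 24.6% of the calls were made again without it and 0% and 1.71% without CUMS-Sal replicates 2 and 3. The 10 splits of the 6 libraries are too few for a share under 0.05; the real one gave 1402 calls and the highest other 1.

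For the other comparisons the splits are also 10 and too few. CUMS-Alb against Ctrl-Sal gave 381 calls and the highest other split 1, CUMS-Flx against Ctrl-Sal 8 and 1, CUMS-Flx against CUMS-Sal 0 and 1, and CUMS-Alb against CUMS-Sal 0 and 0. At least as many calls as the real split were made by 1, 1, 10 and 10 of the 10 splits.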
